A study of Sus scrofa with 2 samples.

How the data were processed

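Single-cell RNA sequencing was carried out on cells of the longissimus dorsi, the long muscle along the back, from piglets of 2 pig breeds: the Guangdong small-eared spotted pig (GDSS) and Yorkshire. Per the labels, the cells were intramuscular vascular stem cells, the stromal and vascular cells of the muscle, taken from 1 g of muscle per piglet. Red blood cells were lysed, dead cells were taken out with magnetic beads, and libraries were made with the 10x Genomics v2 kit and sequenced on a NextSeq-500. There was 1 library per breed. How many piglets went into each library, their sex and the meaning of "P0" in the titles were not given in the sources used here.

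The deposited matrices held raw UMI counts per gene and cell barcode, made with Cell Ranger per the submitters' processing notes, and the matrix headers give software version 3.1.0. The same notes name R 3.5.2 without a role. The genome build and annotation release were not given in the sources used here, so no coordinates are printed. In the deposited count files every barcode had at least 500 UMIs. Both matrices listed the same 21301 features, of which 14846 carried a symbol in the feature list. Of the 6455 others, 680 were given a symbol from a reference table of Ensembl pig identifiers and the rest kept their identifier.

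Barcodes were kept with at least 500 genes detected and at most 10% mitochondrial UMIs. Doublets were scored with scrublet in each library. Its automatic threshold marked 1 GDSS barcode (0.0081%) and 389 Yorkshire barcodes (2.65%), below the 9.83% and 11.8% that the loading would give, and was taken to have failed in GDSS. Cells with a score of at least 0.3 were therefore taken out in both libraries, a value chosen after the scores were seen. This left 10649 of 12286 GDSS and 12763 of 14695 Yorkshire barcodes. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were used with 15 neighbours, and cells of both libraries were clustered together by the Leiden method at resolution 1.0 with no batch correction, which cannot be told from breed here. FAP-like cells were clustered again at resolution 0.5. The tools were Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9. R 4.3.3 with edgeR 4.0.16 was used for TMM factors, a scaling alternative only.

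Clusters were named from marker lists fixed before the data were examined, as were the gene lists, the thresholds, the comparisons and most alternatives. A name needed at least 3 markers that were at least 1.5-fold above all other cells and detected in at least 10% of the cluster's cells. It also needed no more markers of another class than of its own among the 10 leading genes. For the leading genes, a cluster was set against the cells of the other classes, a rule chosen after the clusters were seen. Set against all other cells, 2 FAP-like clusters (0, led by POSTN and THBS4, and 3, led by PTN) lose their name. With that strict naming the FAP-like class held 62.1% of GDSS and 8.06% of Yorkshire cells. Clusters and sub-clusters are given by number, and the genes that define them are not results.

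Cells are not replicates and each breed had 1 library, so there was no test, and no p-value or standard error is given. Raw counts were summed over the cells of a class in each library and scaled to the class total as CPM, with exact Poisson intervals. Folds carry the exact conditional binomial interval, and shares of cells the exact Clopper-Pearson interval, all at 95%. These intervals cover counting error only, not the spread between animals. A count of 0 was set to 3 counts over the summed cells of a class for a fold, which is then a bound. Genes with at least 100 UMIs over both sums entered the lists. For each fixed list the median log2 ratio of GDSS over Yorkshire is given, with the members at least 1.5-fold apart and the percentile of the median among 10000 random lists of the same size and expression. Some genes stand in more than 1 list, such as LPL, PPARG, FABP4, CD36, CXCL8, HEY1 and ACTA2.

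Beside CD9 and PDGFRA, the genes named are up to 4 members of each list with the largest ratio. Added to these are the 12 highest and 12 lowest genes in FAP-like cells among those with a symbol, at least 200 UMIs and at least 20 CPM in the higher library. In the other classes the 4 highest and 4 lowest were taken with at least 100 UMIs, and in the comparison by CD9 detection the 8 highest and 8 lowest of those with the same sign in both libraries. Ribosomal, mitochondrial, haemoglobin, sex-linked and SLA genes were left out of the ranking. Other genes of the fixed lists named in the text were picked after their values were seen. For shares of cells with a CD9 UMI, every cell was thinned at random to 1500 UMIs and shallower cells were left out.

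The ratio, interval, list and thinning steps were tested on simulated data drawn from the FAP-like sums of both libraries, for that comparison, with 9935 genes in the ratio step and 200 of them altered. The intervals held the true ratio for 95.5% of genes, and the direction was right for all genes altered by 1.5, 2 or 4 fold (100%). The counts were drawn with Poisson error, which the intervals assume. The simulation thus does not show how the intervals hold for genes whose UMIs sit in few cells. A list of 12 raised genes reached the percentile 100 and a list of 12 unaltered genes 78.0.

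Alternatives covered the cell filters, doublets, clustering resolution, variable genes, clustering each library alone, scaling, gene filters and thinning depth. Strict cluster naming was kept as an alternative once the main naming rule had been chosen on seeing the clusters. Also added after the data were examined were the automatic doublet threshold, the class without its nerve-sheath-gene clusters, and equal weights per FAP-like sub-cluster, also with sub-clusters made without CD9. The same holds for other classes without cells rich in FAP markers and for satellite-like cells without cluster 8, led by muscle and cell cycle genes. Several list genes, among them IGF2, IGFBP3, MKI67, JUN, IL1B, XIST and MYMX, are not analysed here, and a few ranked or listed genes are not reported here.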

Results

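Single-cell RNA sequencing profiles were collected from the longissimus dorsi of piglets of 2 breeds, the Guangdong small-eared spotted pig (GDSS) and Yorkshire, with 1 library per breed. The series title names intramuscular fat and progenitor cells without the surface tetraspanin CD9. The deposited GDSS matrix held 42093851 UMIs in 12286 barcodes and the Yorkshire matrix 54300953 UMIs in 14695 barcodes. After filtering, 10649 GDSS cells with a median of 2882 UMIs and 1092 genes and 12763 Yorkshire cells with a median of 3005 UMIs and 1120 genes were kept, holding 37781742 and 47324344 UMIs. With 1 library per breed there was no replicate and no test, breed cannot be told apart from the animal, the preparation or the library, and intervals are 95% intervals that cover counting error only.

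The first comparison asked which cells each library held. Fibro-adipogenic progenitor-like cells (FAP-like), the stromal cells of muscle that can form adipocytes and fibroblasts, made up 75.2% (74.4 to 76.0) of GDSS cells and 16.4% (15.7 to 17.0) of Yorkshire cells. Satellite-like cells, the stem cells of muscle fibres, made up 7.33% (6.85 to 7.85) of GDSS cells and 54.7% (53.9 to 55.6) of Yorkshire cells. Endothelial-like cells made up 2.40% (2.12 to 2.71) and 12.3% (11.7 to 12.9). The cells were counted as 8011 and 2090 FAP-like, 781 and 6986 satellite-like, and 256 and 1566 endothelial-like cells in GDSS and Yorkshire.

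Mural-like cells, the pericytes and smooth muscle cells of vessel walls, made up 3.39% of GDSS and 6.24% of Yorkshire cells, and cells with myofibre genes 0.657% and 3.31%. Lymphatic endothelial-like cells made up 0.131% and 0.447%. Glia-like cells with Schwann cell genes made up 4.34% and 3.06%, macrophage-like cells 3.099% and 1.04%, and tenocyte-like cells with tendon genes 2.63% and 2.01%. Cluster 6, 0.789% of GDSS and 0.509% of Yorkshire cells, held endothelial and mural markers together and was left unnamed. No cluster met the marker rule for neutrophils, T or NK cells, B cells, mast cells, adipocytes or erythroid cells. Clustered alone, the GDSS library gave 36.6% FAP-like cells, and several of its clusters then had fewer than 3 markers and no name. The naming rule behind the main shares was chosen after the clusters were seen. Under strict naming, with leading genes set against all other cells, the shares were 62.1% in GDSS and 8.06% in Yorkshire.

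**Figure D1:**
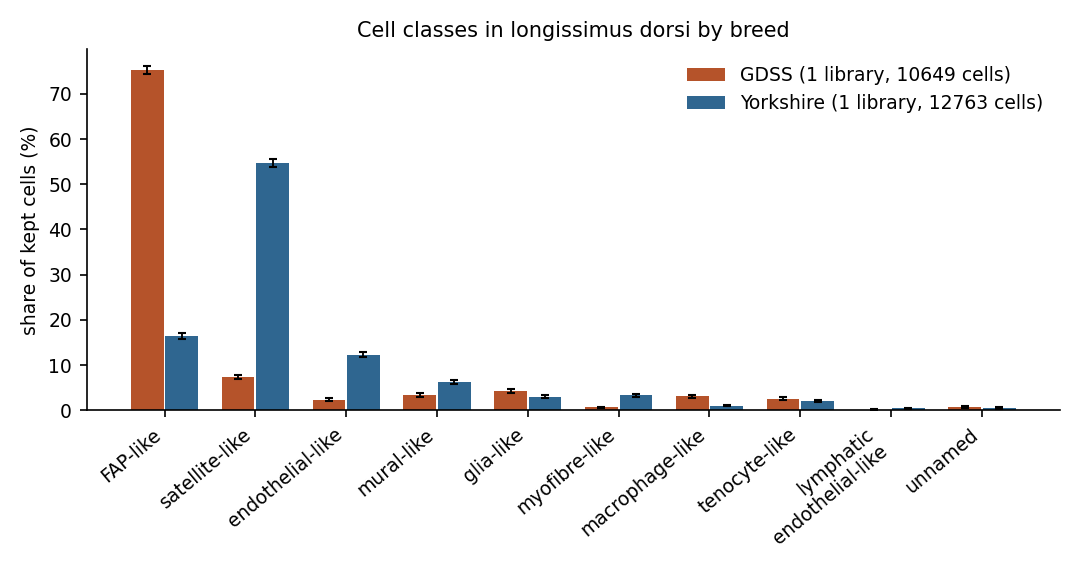
Share of kept cells in each class (percent) in the GDSS and Yorkshire libraries, with exact 95% intervals for counting error. FAP-like cells were 75.2% of the GDSS library and satellite-like cells 54.7% of the Yorkshire library.

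Over all cells summed, marker lists followed these shares. The 8 FAP markers had a median log2 ratio of GDSS over Yorkshire of 1.92, the 8 satellite markers −2.45, the 9 endothelial markers −2.18 and the 9 macrophage markers 0.96. The 8 interferon response genes had a median of −1.60, and all 8 were at least 1.5-fold higher in Yorkshire. The 8 cytokine and chemokine genes had a median of 1.39. The adipogenic regulators, at 0.08, and the lipid handling genes, at −0.35, were also computed over unequal mixtures of cells, so the comparisons that follow were made within classes.

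The second comparison asked how FAP-like cells differed between the breeds. In GDSS FAP-like cells, the list of dissociation stress and immediate early genes and that of cytokine genes had higher medians. The stress list was led by the chaperone gene DNAJB1 at 3.58-fold (3.52 to 3.64). In Yorkshire FAP-like cells, the flavin monooxygenase gene FMO1 was 10.0-fold (9.05 to 11.1) and the membrane protein gene ITM2A 13.4-fold (11.2 to 16.1) higher. The adipogenic regulators had a median of −0.19 and the lipid handling genes one of −0.10, where that of all genes was −0.19. The sums held 27053093 GDSS and 8772107 Yorkshire UMIs, and 9927 genes were measured.

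Different clusters held most of the FAP-like cells of each library. In GDSS, clusters 5 (29.2%), 4 (25.8%) and 1 (16.5%) held most of them, and in Yorkshire clusters 3 (31.6%), 0 (19.2%) and 1 (17.7%). Clusters 4 and 5, with 2070 and 2338 GDSS cells against 168 and 109 Yorkshire cells, were mostly of the GDSS library, and a cluster of 1 library cannot be told apart from that library. The median log2 ratio over all genes was −0.19, and 0.08 with TMM factors or median-of-ratios size factors, so list medians are also given relative to all genes.

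Of the 12 dissociation stress and immediate early genes, 8 were at least 1.5-fold higher in GDSS and 0 in Yorkshire, with a median log2 ratio of 0.79 (0.76 to 0.82), 0.98 above all genes, at percentile 100 of random matched lists. DNAJB1, a co-chaperone induced by heat and handling, stood at 5752 CPM in GDSS and 1606 CPM in Yorkshire. The chaperone genes HSPH1 and HSPA8 were 2.73-fold and 2.53-fold higher in GDSS, and ZFP36, which encodes a protein that destabilises cytokine mRNA, 2.28-fold. Of the 8 cytokine and chemokine genes, 5 were at least 1.5-fold higher in GDSS and 0 in Yorkshire, with a median of 0.83 (0.57 to 1.10), 1.01 above all genes, at percentile 99.98. With equal weights per FAP-like sub-cluster, an alternative chosen after the data were seen, this median was 0.20. The chemokine gene CXCL2 was 3.06-fold higher in GDSS (2.95 to 3.18), the inflammatory cytokine gene IL6 2.41-fold (2.08 to 2.80), and CCL2, which attracts monocytes, 2.07-fold (2.02 to 2.12). CXCL8, also in the macrophage inflammatory list, stood at 7.36 and 3.76 CPM, below the 25.2 and 3.85 CPM estimated for free RNA. The 3 measured macrophage inflammatory genes had a median of 0.60, at percentile 97.79.

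The 12 adipogenic regulators had a median log2 ratio of −0.19 (−0.32 to −0.00) at percentile 39.22, which was 0.07 with TMM factors or median-of-ratios size factors. It was −0.63 with cells thinned to 1500 UMIs and −0.53 with at least 500 UMIs per gene, where the medians of all genes were −0.16 and −0.14. Of the 12, 4 were at least 1.5-fold higher in Yorkshire and 1 in GDSS. KLF15, CEBPD and KLF5, transcription factor genes of adipocyte differentiation, were 2.03-fold (1.65 to 2.51), 2.01-fold (1.79 to 2.25) and 1.95-fold (1.82 to 2.10) higher in Yorkshire, and CEBPB, an early factor of the same programme, was 1.71-fold higher in GDSS. PPARG, the master regulator of fat cell formation, stood at 7.54 CPM in GDSS and 9.69 CPM in Yorkshire, a ratio of 1.28 (0.986 to 1.66). The 12 measured lipid handling genes had a median of −0.10 (−0.31 to 0.03) at percentile 62.55, which was 0.16 with either scaling. The fatty acid binding protein gene FABP4, which is also a capillary marker, stood at 11.9 and 54.1 CPM and FABP5 at 33.1 and 74.8 CPM. Free RNA, estimated after the data were seen from the level of other classes' markers in FAP-like cells, would give 10.7 and 83.0 CPM of FABP4 and 39.7 and 106 CPM of FABP5, so the levels of both were at or near background. LPL, the lipoprotein lipase gene, was 1.47-fold higher in Yorkshire (1.42 to 1.52). FASN, which encodes the fatty acid synthase, was 1.33-fold higher in GDSS.

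Of 8 measured anti-adipogenic genes, 2 were higher in each library, with a median of 0.30 (0.19 to 0.49), 0.49 above all genes, at percentile 99.56. KLF2, which represses PPARG, was 1.81-fold higher in GDSS and DLK1, a preadipocyte inhibitor of differentiation, 1.78-fold (1.54 to 2.06). SOX9 and WNT5A were 2.64-fold (2.10 to 3.32) and 1.73-fold higher in Yorkshire. Of 11 measured committed preadipocyte genes, 3 were at least 1.5-fold higher in GDSS, with a median of 0.16 (0.07 to 0.19) at percentile 93.98, which was −0.11 with each library clustered alone. The adhesion gene ICAM1 stood at 251 and 62.9 CPM, the coagulation factor gene F3 was 2.32-fold higher and the basement membrane collagen gene COL15A1 2.03-fold higher in GDSS. FMO2 was 1.47-fold higher in Yorkshire. LPL and PPARG belong to this list too. The 6 measured genes of PI16-type progenitors, the least committed stromal cells, had a median of −0.29 (−0.34 to −0.21) at percentile 13.11, 0.05 with each library clustered alone. DPP4, a surface peptidase of these progenitors, was 1.56-fold higher in Yorkshire.

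Of the 19 collagen and fibrosis genes, 5 were at least 1.5-fold higher in Yorkshire and 1 in GDSS. Their median of −0.25 (−0.27 to −0.19), at percentile 2.5, was 0.02 with TMM factors or median-of-ratios size factors. The matrix genes FBN1 (2.72-fold) and LOX (2.01-fold), for fibrillin and a collagen crosslinking enzyme, were higher in Yorkshire. The smooth muscle actin gene ACTA2 stood at 7.87 and 23.0 CPM, below the 15.5 and 31.9 CPM estimated for free RNA. CCN2, a matricellular growth factor gene, was 3.09-fold higher in GDSS (2.88 to 3.33). COL1A1, COL1A2 and COL3A1 are in this list and among the FAP markers, whose 8 genes had a median of 0.09 at percentile 74.73. The 4 complement genes had a median of −0.60 (−0.77 to −0.43), −0.42 relative to all genes, at percentile 1.38. With equal weights per sub-cluster this median was −0.15, where that of all genes was −0.09. The central complement gene C3 was 2.999-fold higher in Yorkshire (2.60 to 3.46) and the terminal pathway gene C7 2.05-fold, while CFD, the adipsin gene, was 1.51-fold higher in GDSS.

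The 8 genes of the insulin-like growth factor axis had a median of −0.28 (−0.35 to −0.17) at percentile 14.06. The receptor gene IGF1R was 1.63-fold higher in Yorkshire, and the binding protein genes IGFBP2 and IGFBP6 were 1.86-fold and 1.44-fold higher in GDSS. The 6 interferon response genes had a median of −0.31 (−0.52 to −0.21) at percentile 28.91, which was 0.02 when only genes with at least 500 UMIs entered. The antiviral genes MX1 (1.81-fold) and IFIT1 (1.80-fold) were higher in Yorkshire, and the ubiquitin-like modifier gene ISG15 was 1.58-fold higher in GDSS. The 8 glycolysis and hypoxia genes had a median of −0.20 at percentile 30.33, which was 0.07 with either scaling, and the vasodilator peptide gene ADM was 1.79-fold higher in GDSS. The 5 measured cell cycle genes had a median of 0.10 (−0.21 to 0.37), with STMN1, which encodes a microtubule regulator, 2.17-fold higher in Yorkshire.

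Markers of other cells also differed. The 4 glia markers had a median of −2.05 at percentile 0.01. The 5 satellite markers had a median of −0.84 (percentile 0.59), the 6 myofibre markers −0.88 (0.02) and the 6 tenocyte markers −0.77 (0.19). Under strict naming the tenocyte median was 0.25. MYOD1, the muscle commitment factor gene, stood at 0.961 and 9.01 CPM, where free RNA would give 0.524 and 5.72 CPM, and the myosin light chain gene MYL1 was 2.69-fold higher in Yorkshire FAP-like cells. The satellite quiescence genes had a median of −0.42 (percentile 7.4), the satellite commitment genes −0.92 (0.87), the endothelial capillary genes −0.29 (21.47) and the mural markers −0.27 (32.32), which was 0.17 with equal weights per sub-cluster. These medians varied with the processing, at −0.033 for quiescence genes without the nerve-sheath-gene clusters, −0.044 for commitment genes with strict naming, and −2.19 for capillary genes when genes with at least 20 UMIs entered. Too few genes of the resident macrophage list and of the endothelial arterial and venous lists were measured for a median. The mitochondrial genes had a median of 0.00. The 59 ribosomal protein genes had a median of −0.24 at percentile 0.01, which was 0.03 with TMM factors and 0.02 with median-of-ratios size factors.

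**Figure D2:**
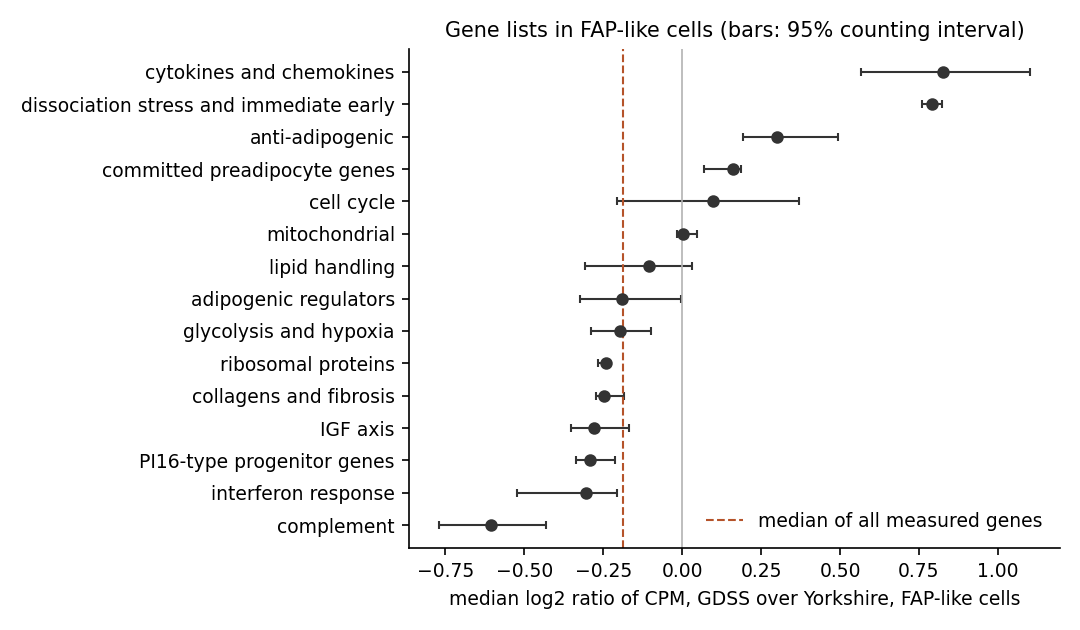
Median log2 ratio of GDSS over Yorkshire in FAP-like cells for the fixed gene lists other than those of satellite, macrophage and endothelial cells and of markers, with the 95% interval for counting error; scaling moves the median of all genes from −0.19 to 0.08. Cytokine genes at 0.83 and stress genes at 0.79 lie above the other lists drawn, and complement genes at −0.60 below them.

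Among all ranked genes, the leucine-rich repeat gene LRRC23 (6.56-fold, 4.46 to 10.0) and ARHGDIB (6.38-fold, 4.56 to 9.18) had the largest ratios in favour of GDSS, both below 30 CPM. The small heat shock protein gene CRYAB stood at 483 and 94.05 CPM (5.13-fold, 4.79 to 5.52) and CCN1, a matricellular gene induced by growth factors, at 1767 and 467 CPM (3.79-fold, 3.67 to 3.91). The osteopontin gene SPP1 was 4.07-fold higher in GDSS (3.06 to 5.50), and the interferon regulatory factor gene IRF8, which led a sub-cluster of mostly GDSS cells, 3.89-fold (3.33 to 4.55). The immediate early gene ARC was 3.90-fold higher, TP53RK 4.08-fold, the folate receptor gene FOLR1, near its free RNA estimate of 36.6 CPM in GDSS at 49.6 CPM, 3.85-fold and the enolase gene ENO2 3.82-fold. With equal weights per sub-cluster the log2 ratio was 1.60 for LRRC23 (main value 2.71), 1.26 for TP53RK (2.03), 1.22 for CCN1 (1.92), 1.09 for ENO2 (1.93) and 1.05 for ARC (1.96).

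The keratin gene KRT8 had 0 UMIs in GDSS and 930 in Yorkshire, at least 956-fold higher, but in only 59 cells, and 10 of them held 60.9% of the UMIs. KRT18, its partner keratin, had 2 and 359 UMIs, a ratio of 554 (152 to 4589), with 78.8% of the Yorkshire UMIs in 10 cells. Both sat almost wholly in cluster 2, as did MPZL2, an adhesion gene (38.5-fold, 24.95 to 62.5). ITM2A stood at 5.66 and 75.7 CPM. GSTM3, a glutathione transferase gene, was 11.0-fold higher in Yorkshire (8.15 to 15.2), the matrix gene SBSPON 16.4-fold, and GFRA2, a neurotrophic factor receptor gene, 10.3-fold (7.90 to 13.7). FMO1 stood at 19.1 and 191 CPM, the Wnt inhibitor gene SFRP1 at 12.6 and 115 CPM (9.15-fold, 8.09 to 10.4), the integrin gene ITGB4 at 5.17 and 47.8 CPM, and the aldehyde oxidase gene AOX1 at 4.29 and 33.2 CPM. Cluster 2 also held 85.7% of the Yorkshire UMIs of SBSPON, 82.4% of GFRA2, 81.6% of ITGB4 and 80.4% of SFRP1. With CLDN1 among its leading genes, it is a nerve-sheath-gene cluster, and it held 9.24% of GDSS and 14.2% of Yorkshire FAP-like cells. FMO1, SFRP1, ITGB4, AOX1, IRF8 and ICAM1 also lead sub-clusters that differ in share between the libraries. With equal weights per sub-cluster the log2 ratio was −2.73 for FMO1, −2.40 for SFRP1, −2.13 for ITGB4, 2.51 for CRYAB and 1.02 for IRF8. Without the nerve-sheath-gene clusters it was −1.31 for SFRP1. With at most 5% mitochondrial UMIs it was −1.77 for SFRP1, −1.75 for GFRA2 (main value −3.37) and −1.16 for ITGB4, and with each library clustered alone −5.88 for ITGB4.

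**Figure D3:**
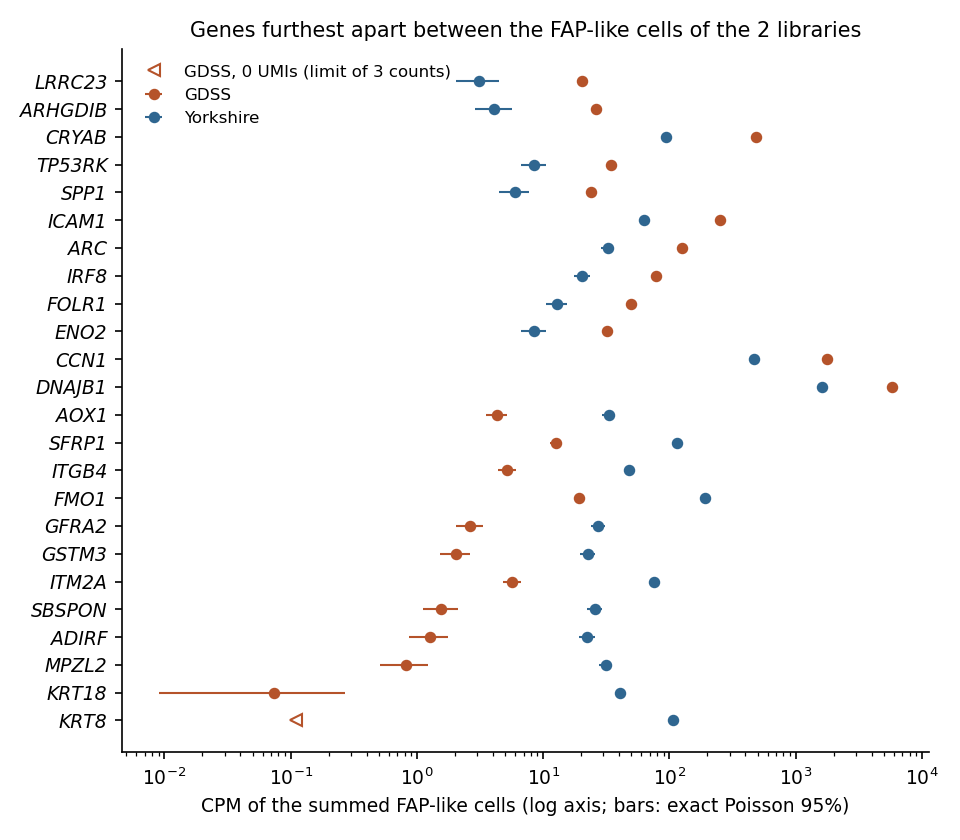
CPM of the summed FAP-like cells of each library (log axis, exact Poisson 95% bars) for the 12 ranked genes furthest towards each library. CRYAB stood at 483 CPM in GDSS and 94.05 CPM in Yorkshire, and KRT8, with 0 UMIs in GDSS, is drawn there at 3 counts.

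The third comparison asked how FAP-like states were shared out. In the second clustering of FAP-like cells, 64.0% of the cells of each library would have to move for the shares to match. Sub-cluster 1, led by PBK, IRF8 and ALDH1A1, held 29.5% of GDSS and 1.63% of Yorkshire FAP-like cells, sub-cluster 2, led by CCL2 and CXCL2, 19.8% and 2.92%, and sub-cluster 3, led by FBLN2, CCL26 and the progenitor gene PI16, 18.1% and 3.54%. Sub-cluster 5, led by FMO1, CD36 and VCAM1, held 6.18% and 29.5%, and sub-cluster 8, led by FMO1, ADAMTS5 and FBN1, 0.125% and 20.5%. Sub-cluster 4, led by the tendon and matrix genes TNMD, KERA and COL11A1 and by CD9, held 10.4% and 20.9%. Sub-cluster 6, led by ANGPTL7, ITGB4 and CLDN1, held 4.86% and 12.4%, sub-cluster 7, led by SFRP4, HHIP and RBP4, 4.33% and 4.55%, and sub-cluster 9, led by KANK3, HSPA6 and ICAM1, 4.89% and 0.239%. Sub-cluster 10, with myofibre genes, held 1.15% and 3.06%. Sub-clusters 11 and 12 held under 0.5% of the cells of either library.

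The fourth comparison asked how many FAP-like cells had CD9 RNA, since the series title names progenitor cells without surface CD9. Surface CD9 protein was not measured here, and detection of a CD9 UMI does not stand for it. With every cell thinned to 1500 UMIs, CD9 (ENSSSCG00000022230) was detected in 10.0% (9.36 to 10.7) of 7433 GDSS and 16.02% (14.4 to 17.7) of 1998 Yorkshire FAP-like cells. Cells without a detected CD9 UMI were thus the larger part in both breeds. In the sums CD9 stood at 142 CPM (137 to 146) in GDSS and 218 CPM (209 to 228) in Yorkshire, 1.54-fold higher in Yorkshire (1.46 to 1.63), a log2 ratio of −0.63. PDGFRA (ENSSSCG00000008841), the receptor gene used to recognise FAPs, had a log2 ratio of −0.02, which was 0.24 with either scaling. With equal weights per FAP-like sub-cluster the CD9 shares were 13.2% and 15.1% and the log2 ratio of CD9 was −0.02, but CD9 itself leads sub-cluster 4. With sub-clusters made without CD9, also chosen after the data were seen, the shares were 13.3% and 14.2% at resolution 0.5, 11.9% and 15.7% at resolution 0.3, and 16.8% and 16.4% at resolution 0.8. With each library clustered alone the GDSS share was 16.4% and the log2 ratio −0.00. In that setting several GDSS clusters had no name, so these values cover fewer GDSS FAP-like cells than the main ones.

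CD9 detection varied more between FAP-like clusters than between breeds. In cluster 0, led by POSTN and THBS4, 53.3% of GDSS and 49.9% of Yorkshire cells had a CD9 UMI. In cluster 5 these shares were 1.35% and 2.91%, and in cluster 3 1.84% and 4.82%. In cluster 1, with PI16 and MFAP5 among its leading genes, they were 11.0% and 8.24%. Shares depended on depth, at 7.37% and 12.5% when thinned to 1000 UMIs and 15.2% and 23.1% when thinned to 2500 UMIs. Median depth before thinning was 2947 and 3620.5 UMIs in FAP-like cells. Every other class had a CD9 UMI in a larger share of cells in GDSS, and all but the endothelial-like class, at 15.4%, did in Yorkshire. CD9 was detected in 18.1% of endothelial-like GDSS cells, whose median depth was 2700.5 UMIs in GDSS and 3019 UMIs in Yorkshire, in 95.1% and 92.0% of glia-like, 84.6% and 89.1% of lymphatic endothelial-like, 59.3% and 52.4% of mural-like, 49.1% and 47.5% of satellite-like, 48.4% and 47.9% of tenocyte-like, 32.5% and 24.2% of macrophage-like and 28.9% and 38.3% of myofibre-like cells. No class is known to lack CD9, so free RNA was estimated from markers of other classes, at 21.1 CPM of CD9 in GDSS and 31.9 CPM in Yorkshire FAP-like cells.

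**Figure D4:**
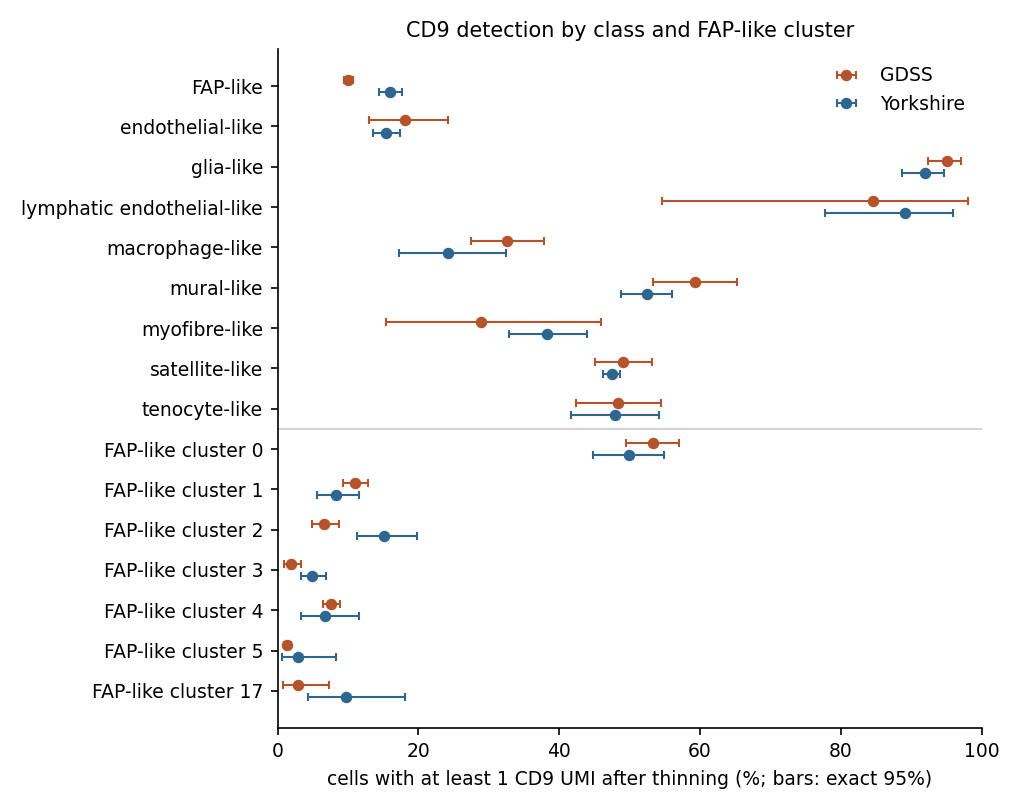
Share of cells with at least 1 CD9 UMI (percent) after thinning to 1500 UMIs, by class and by FAP-like cluster, in GDSS and Yorkshire, with exact 95% intervals. All FAP-like cells stood at 10.0% and 16.02%, and cluster 0 at 53.3% and 49.9%.

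The fifth comparison asked how FAP-like cells without a detected CD9 UMI differed from those with one, within each library. In both breeds the undetected cells had higher medians of the lipid handling and committed preadipocyte lists and a lower median of the collagen and fibrosis list. The committed preadipocyte genes had a median log2 ratio of undetected over detected cells of 1.34 in GDSS and 1.29 in Yorkshire, both at percentile 100, and 7 of 10 measured genes in GDSS and 7 of 9 in Yorkshire were at least 1.5-fold higher in undetected cells. The lipid handling genes had medians of 0.63 and 0.48, at percentiles 100 and 99.52, and the adipogenic regulators 0.34 and 0.36, at 98.02 and 97.69. Against its list, the lipid handling gene FABP5 was 2.47-fold higher in detected GDSS cells and 2.50-fold higher in detected Yorkshire cells. The collagen and fibrosis genes had medians of −0.49 and −0.40, both at percentile 0.00, while the basement membrane collagen genes COL4A1 and COL4A2, of the committed preadipocyte list, were higher in undetected cells, with log2 ratios of 1.43 and 1.34 in GDSS and 1.43 and 1.11 in Yorkshire. The myofibre markers had medians of 0.31 in GDSS, at percentile 90.58, and 1.67 in Yorkshire, at percentile 100. The groups held 6687 and 746 GDSS cells and 1678 and 320 Yorkshire cells.

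LPL, the gene for the enzyme that releases fatty acids from lipoproteins, stood at 475 CPM in undetected and 193 CPM in detected GDSS cells, and at 807 and 329 CPM in Yorkshire. APOD, a lipid carrier gene, stood at 2950 and 790 CPM in GDSS and 4972 and 1458 CPM in Yorkshire. COL15A1 stood at 714 and 199 CPM and at 438 and 144 CPM, and the chemokine gene CXCL14 at 254 and 73.3 CPM and at 298 and 131 CPM. CXCL12, the stromal homing chemokine gene, stood at 362 and 138 CPM in GDSS and 431 and 138 CPM in Yorkshire. EBF2, a regulator of adipocyte identity, stood at 92.6 and 55.4 CPM and at 146 and 91.7 CPM.

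Of the ranked genes higher in undetected cells in both libraries, the surface peptidase gene MME stood at 78.2 and 15.2 CPM in GDSS and 97.3 and 10.4 CPM in Yorkshire, and another surface peptidase gene, ENPEP, at 63.9 and 20.6 CPM and at 41.7 and 10.4 CPM. The hedgehog inhibitor gene HHIP stood at 27.9 and 12.5 CPM and at 41.3 and 4.17 CPM. FSTL5, ADAM19 and FMO2 were also among the 8 highest. The corneal and tendon proteoglycan gene KERA was 7.27-fold higher in detected GDSS cells and higher by 5.28-fold in Yorkshire. SFRP4, a Wnt inhibitor gene, stood at 15.5 and 127 CPM and at 77.5 and 304 CPM, COL11A1, a fibrillar collagen gene, at 10.6 and 59.0 CPM and at 34.6 and 179 CPM, and the fibromodulin gene FMOD at 80.8 and 217 CPM and at 69.1 and 323 CPM. THBS2, CTHRC1, CPE and DHRS3 were also among the ranked genes higher in detected cells, and COL1A2 stood at 8361 and 16408 CPM in GDSS and 9172 and 18690 CPM in Yorkshire.

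Among the other lists, the anti-adipogenic genes had medians of 0.49 in GDSS and 0.03 in Yorkshire, the interferon genes 0.77 and 0.33, the complement genes 0.71 and 0.39, the insulin-like growth factor axis 0.27 and −0.13, the PI16-type genes 0.02 and 0.22, the cytokines 0.09 and 0.31, the stress genes 0.12 and −0.09, and the glycolysis genes −0.12 and 0.20. The GDSS complement median was −0.06 when cells were thinned to 1000 UMIs. Across 3452 genes, which are not independent replicates, 61.9% had the same sign in both libraries and the Pearson correlation of the log2 ratios was 0.57. Of the detected cells, 59.5% in GDSS and 66.9% in Yorkshire had exactly 1 CD9 UMI, so an undetected cell is not a cell without CD9 RNA. Cluster 0 with its matrix genes held 365 of the 746 detected GDSS cells and 195 of the 320 in Yorkshire. Only sub-cluster 4 could be split in both libraries, and within it the GDSS lipid handling median was 0.18. Sub-clusters 5 (495 GDSS and 617 Yorkshire cells) and 6 (389 and 260) had too few CD9-detected or undetected cells in at least 1 library.

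**Figure D5:**
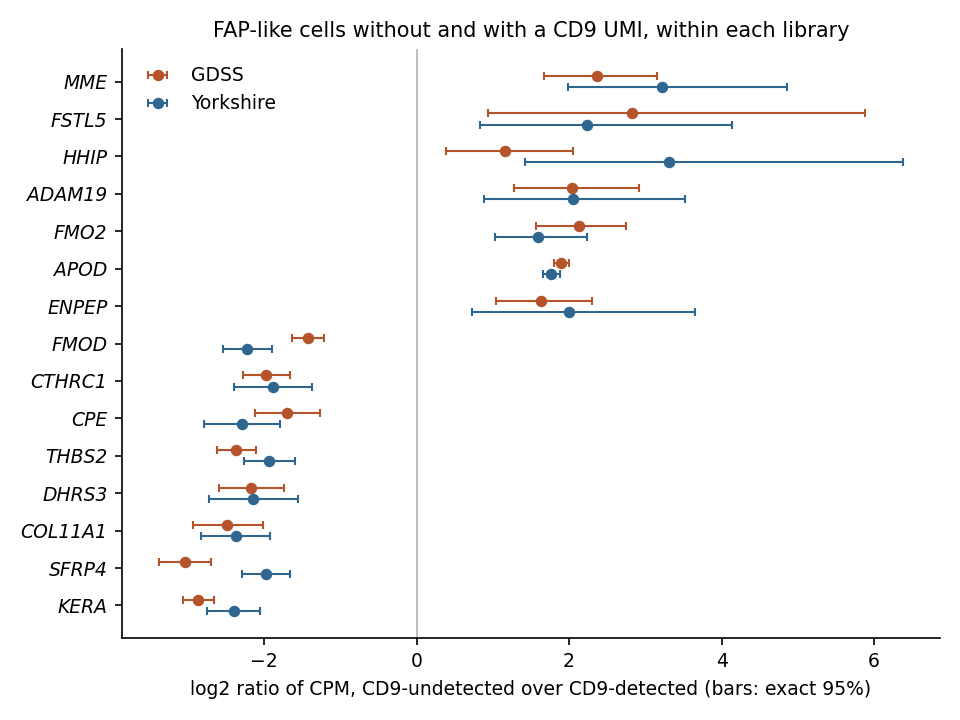
Log2 ratio of CD9-undetected over CD9-detected FAP-like cells in GDSS and Yorkshire, thinned to 1500 UMIs, for ranked genes furthest each way, with exact 95% intervals. APOD lies at 1.90 in GDSS and 1.77 in Yorkshire.

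The remaining comparisons were made within the other classes with at least 100 cells in both libraries. The median of the FAP markers was higher in GDSS in each of them. The median log2 ratios were 1.92 in endothelial-like, 2.79 in macrophage-like, 2.77 in satellite-like, 1.43 in glia-like, 1.07 in mural-like and 0.24 in tenocyte-like cells. In tenocyte-like cells it was at percentile 89.3. Without cells rich in these markers the median was −0.34 in glia-like cells. Without such cells it was 1.36 in endothelial-like, 1.60 in macrophage-like, 0.68 in satellite-like and 0.20 in mural-like cells.

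In endothelial-like cells, interferon response genes were higher in Yorkshire. Mural markers were higher in GDSS, with a median of 2.34 at percentile 100 and 4 of 4 genes at least 1.5-fold higher, and the 9 endothelial markers had a median of −0.35 (percentile 2.95). Of 8 interferon response genes, 7 were at least 1.5-fold higher in Yorkshire, with a median of −1.31 (−1.47 to −1.09) at percentile 0.00. The antiviral genes MX1 (3.55-fold), RSAD2 (3.31-fold), MX2 (3.07-fold) and IFIT1 (2.82-fold) led this list. The 5 capillary genes had a median of −0.50 (percentile 2.34), with CA4, the capillary carbonic anhydrase gene, at 148 and 543 CPM and FABP4 at 2921 and 7615 CPM. The 5 arterial genes had a median of −0.73 (1.30) and the 3 venous genes 0.10. With each cell weighted equally the medians were 1.15 for mural markers, −0.048 for endothelial markers, −0.24 for capillary, −0.32 for arterial and −0.06 for venous genes. The median was −0.65 (0.21) for the 8 genes of the insulin-like growth factor axis. The stress list had a median of −0.12 (17.9), which was 0.05 with each cell weighted equally, and the collagen genes 1.20. RAMP3, which encodes a subunit of the adrenomedullin receptor, had 1 UMI in GDSS and 220 in Yorkshire. The proteoglycan gene LUM was 11.5-fold higher in GDSS, with 86.0% of its GDSS UMIs in 10 cells, and the urokinase gene PLAU 11.1-fold, with 97.4% of its GDSS UMIs in 10 cells.

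In macrophage-like cells, the medians of the resident macrophage, interferon and stress lists were higher in Yorkshire. Markers of other cells were higher there too, with medians of −2.59 (percentile 0.00) for 5 myofibre and −0.93 (1.0) for 3 T and NK cell markers, and the 9 macrophage markers had a median of −0.32 (6.1). The 6 resident genes had a median of −0.70 (percentile 0.74). The mannose receptor gene MRC1 (2.14-fold), the hyaluronan receptor gene LYVE1 (1.90-fold), which is also a lymphatic marker, the folate receptor gene FOLR2 (1.72-fold) and the haemoglobin scavenger receptor gene CD163 (1.53-fold) were higher in Yorkshire. The inflammatory genes were split, with a median of −0.19, which was −0.86 with each cell weighted equally, TNF 5.50-fold higher in Yorkshire, and CXCL8 (2.70-fold) and IL1A (1.69-fold) higher in GDSS. The interferon list had a median of −0.78 (percentile 0.27). The stress list had a median of −0.69 (0.06), opposite in sign to that in FAP-like cells, with the immediate early gene FOS 3.16-fold higher in Yorkshire. The lectin receptor gene CD209 stood at 105 and 948 CPM. Of the 330 GDSS cells, 28 (8.48%) were rich in FAP markers and held 76.2% of the FAP marker UMIs of the class.

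In mural-like cells, the medians of the stress, lipid handling and cytokine lists were higher in GDSS. The stress list had a median of 0.62 (percentile 99.96), 7 of 12 genes being at least 1.5-fold higher, with ATF3, a stress-induced transcription factor gene, 1.88-fold and DNAJB1 1.996-fold higher. The lipid handling genes had a median of 0.63 (99.90), 4 of 7 genes being at least 1.5-fold higher in GDSS and 1 in Yorkshire, with LPL 3.09-fold and FABP5 2.69-fold higher in GDSS and the apolipoprotein gene APOE 2.44-fold higher in Yorkshire. The cytokine genes had a median of 0.74 (99.88), 2 of 4 genes being at least 1.5-fold higher, with CXCL12 3.85-fold and IL6 1.88-fold higher in GDSS. The surface peptidase gene ENPEP was 5.38-fold higher in GDSS.

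Satellite-like cells were shared out differently over clusters 7 (45.8% in GDSS, 25.6% in Yorkshire), 9 (27.7%, 33.8%), 10 (20.7%, 37.9%) and 8 (5.76%, 2.71%), and no value was computed with equal weights per cluster. Of 10 measured cell cycle genes, 6 were at least 1.5-fold higher in GDSS, with a median of 1.51 (percentile 100), UBE2C, a mitotic ubiquitin-conjugating enzyme gene, 9.81-fold and the survivin gene BIRC5 4.31-fold higher. Cluster 8 was led by the muscle genes ACTC1 and MYMK and by cell cycle genes such as TOP2A. Without this cluster the cell cycle median was −0.44, and without cells rich in FAP markers it was 0.18. The quiescence genes had a median of 0.39 (97.58), with SPRY1, a growth factor signalling inhibitor gene, 1.48-fold higher in GDSS. The commitment genes had a median of 0.39 (94.44), −0.55 without cluster 8, with the fusion gene MYMK 2.23-fold higher in GDSS, and MYOD1 (1.63-fold) and the cell cycle inhibitor gene CDKN1A (1.60-fold) higher in Yorkshire. The lipid handling genes (0.29) and collagens (0.62) had medians of −0.13 and −0.06 without cluster 8. NRN1, which encodes neuritin, had 0 UMIs in GDSS and 993 UMIs in 737 Yorkshire cells, at least 30.5-fold higher, and CYP2B22, a cytochrome P450 gene, was 9.20-fold higher in Yorkshire.

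In glia-like cells, the cholecystokinin gene CCK stood at 795 CPM in GDSS and 20.2 CPM in Yorkshire (39.3-fold, 26.1 to 62.4) and was detected in 145 of 462 and 12 of 391 cells. The peripheral myelin lipid protein gene PMP2 was 6.13-fold higher in Yorkshire. The glia markers had a median of −0.70, the 3 measured cytokine genes 1.13 (percentile 99.77), with CCL2 7.79-fold higher in GDSS, where 10 cells held 89.0% of its UMIs, and the hyaluronan-binding gene TNFAIP6 2.19-fold higher, and the lipid handling genes −0.53. In tenocyte-like cells, the chromatin gene HMGA1 stood at 143 and 10.0 CPM, 14.3-fold higher in GDSS. The lipid handling genes had a median of −0.59 (percentile 1.86), with FABP5 3.42-fold higher in GDSS and APOE 2.28-fold higher in Yorkshire. The cytokine genes had a median of −0.69 (1.74), with CCL2 3.86-fold higher in Yorkshire. ITM2A had 0 UMIs in GDSS tenocyte-like cells, at least 44.3-fold higher in Yorkshire.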

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

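The test of handling of the whole GDSS library was chosen only after the result was seen.

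These lists had medians of opposite sign in different classes, with a median of at least 1.5-fold in each direction, and the differences between classes were not tested. The lipid handling genes had a median log2 ratio of GDSS over Yorkshire of 0.63 in mural-like and −0.59 in tenocyte-like cells. The cytokine and chemokine genes had a median of 1.13 in glia-like cells, over 3 measured genes, and −0.69 in tenocyte-like cells. The dissociation stress and immediate early genes had a median of 0.79 in FAP-like and −0.69 in macrophage-like cells.

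The stress genes of FAP-like cells are a pattern to follow, since DNAJB1, HSPH1 and HSPA8 are also induced by the digestion of tissue. If all classes respond alike, which was not tested, harsher handling of the whole GDSS library would raise the list in every class. The median of −0.69 in macrophage-like cells then argues against handling as the whole source, but this rule was set with that value known. The list was also higher in GDSS in mural-like (0.62), satellite-like (0.38) and tenocyte-like (0.37) cells, but near 0 in endothelial-like (−0.12) and glia-like (0.02) cells, so handling as part of the difference stays open. A different make-up of the FAP-like cells was tested with equal weights per sub-cluster, where 71.3% of the median was left, at 0.56. This lies between the bounds set, so the make-up cannot be told apart from a difference within sub-clusters. A difference between the breeds stays open and was not tested.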

How the results depend on the processing

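The main naming rule was chosen after seeing the clusters, with strict naming kept as its alternative. Also chosen after seeing the data were the automatic doublet threshold and equal weights per sub-cluster, also with sub-clusters made without CD9. The same holds for leaving out nerve-sheath-gene clusters, FAP-marker-rich cells or cluster 8 of the satellite-like cells. No paired analysis was possible because each breed had 1 library, both with replicate number 1, and leaving out a replicate was not possible either.

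The FAP-like share of cells in percent, GDSS (75.2%), was 73.8% with at least 200 genes, 77.2% with at least 1000 genes, 73.9% with at most 20% mitochondrial UMIs, 73.1% with doublets kept, 73.6% at resolution 2.0, 72.4% with the automatic doublet threshold, 66.9% without nerve-sheath-gene clusters, 62.1% with strict naming and 36.6% with each library clustered alone. The FAP-like share of cells in percent, Yorkshire (16.4%), was 19.6% with at least 1000 genes, 15.04% with doublets kept, 15.5% at resolution 2.0, 15.1% with the automatic threshold, 13.4% without nerve-sheath-gene clusters and 8.06% with strict naming. It was higher in GDSS under each of these alternatives.

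The share of FAP-like cells with CD9 in GDSS (10.0%) was 11.5% with at least 1000 genes, 11.7% with at most 5% mitochondrial UMIs, 16.4% with each library clustered alone, 5.98% with strict naming, 7.37% and 15.2% when thinned to 1000 and 2500 UMIs, 14.7% not thinned, 8.80% with at least 2 UMIs 13.2% with equal weights per sub-cluster and 13.3% with equal weights per sub-cluster made without CD9. In Yorkshire (16.02%) it was 9.55% with strict naming, 12.5% and 23.1% when thinned to 1000 and 2500 UMIs, 27.8% not thinned and 14.2% with equal weights per sub-cluster made without CD9. The share of FAP-like cells in different sub-clusters was 69.5% at resolution 0.3.

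In FAP-like cells the adipogenic median (−0.19) was 0.074 with TMM factors and 0.070 with median-of-ratios size factors, −0.53 with at least 500 UMIs and −0.63 with thinned cells. The lipid handling median (−0.10) was 0.13 with strict naming, 0.16 with TMM factors and 0.16 with median-of-ratios size factors. Among medians in the outer 5% of random lists and with an interval clear of 0, the sign changed for collagens (−0.25), at 0.0013 with each library clustered alone, 0.020 with TMM factors and 0.016 with median-of-ratios size factors, ribosomal proteins (−0.24), at 0.025 and 0.021 with these scalings, and tenocyte markers (−0.77), at 0.25 with strict naming.

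Of such medians elsewhere, the sign changed for collagens in glia-like cells (−0.17 with cells weighted equally, −0.22 without FAP-marker-rich cells), FAP markers in glia-like cells (−0.34 without these cells), macrophage inflammatory genes over all cells (−0.12 with cells weighted equally), and in satellite-like cells for lipid handling (−0.047 without FAP-marker-rich cells, −0.13 without cluster 8), collagens (−0.057) and cell cycle genes (−0.44) without that cluster. In the CD9-undetected against detected GDSS cells, the complement median was −0.058 when thinned to 1000 UMIs and the lipid handling median 0.18 within sub-cluster 4. The shift with scaling follows from 1 factor for all genes, and the CD9 shares at other thinning from depth. For all others the cause was not tested.

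Of 426 alternative values of the FAP-like list medians, 271 stayed within the counting interval of the main value and 24 had the other sign, among them collagens, PI16-type, committed preadipocyte, cell cycle, interferon, glycolysis, mitochondrial, ribosomal, mural and tenocyte genes. These numbers were 356 and 5 of 471 for named FAP-like genes, where PDGFRA accounts for all 5, 319 and 43 of 520 for lists in other classes, 104 and 22 of 156 for the comparison by CD9 detection, and 132 of 192 for other class shares. The stress median in FAP-like cells ranged from 0.56 to 1.06 and the cytokine median from 0.20 to 1.09. Depth limits genes with few UMIs and CD9 detection per cell.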

Other observations

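The tests of doublets with a satellite-like cell and of cycling FAP-like cells in the satellite-like class were chosen only after the result was seen, as were the sub-clusters made without CD9 and the genes named here for their ratios across classes.

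Several genes were higher in Yorkshire across unlike classes. The log2 ratio of ITM2A was −3.74 in FAP-like, −2.70 in mural-like, −1.45 in satellite-like and −0.85 in endothelial-like cells. The glutathione transferase gene GSTM3 stood at −3.47 in FAP-like, −3.24 in mural-like, −3.01 in glia-like, −2.63 in satellite-like and −0.51 in endothelial-like cells. CYP2B22 stood at −3.41 in FAP-like, −3.20 in satellite-like, −2.88 in mural-like and −1.59 in endothelial-like cells. No explanation was tested for these genes.

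ADIPOQ, the adiponectin gene of fat cells, stood at 81.6 CPM in GDSS satellite-like cells and 0.630 CPM in Yorkshire, with its GDSS UMIs in 7 cells and 98.2% of them in cluster 8. No adipocyte-like cluster was named. GNLY, a granule gene of cytotoxic lymphocytes, had 215 UMIs in 2 Yorkshire macrophage-like cells and 0 in GDSS. Transcripts of the Y-linked genes KDM5D (154 and 151 UMIs), EIF1AY (1208 and 1833) and ZFY (1051 and 1335) were present in both libraries.

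The median of the FAP marker genes was higher in the other classes of the GDSS library, with log2 ratios of 2.77 in satellite-like and 2.79 in macrophage-like cells. Free RNA would keep the markers in 1 ratio, which 21 of 24 pairs of marker and class did, but it would also spread with depth, and the 5% of cells with most FAP marker UMIs held 77.2% of them against 22.2% if spread by depth, which argues against free RNA as the whole source. The 77.2% is what doublets would also give. By class it was 76.5% in satellite-like, 60.9% in endothelial-like and 58.7% in macrophage-like GDSS cells. In Yorkshire these values were 24.3%, 53.5% and 52.2%, so endothelial-like and macrophage-like cells were nearly as concentrated there. In satellite-like cells rich in FAP markers 9.96% of the satellite marker level was left, which argues against doublets with a satellite-like cell. Of these cells, 70.0% lay in cluster 8, led by muscle genes as well as cell cycle genes, so they may be cycling FAP-like cells placed in that class. Cell cycle genes were not measured in these cells alone. A difference between the breeds stays open, as untested.

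CD9 was detected in a lower share of FAP-like cells in GDSS. Free RNA from CD9-rich classes would give 14.1% of the difference of 76.8 CPM, which argues against it as the source. With equal weights per FAP-like sub-cluster, 31.8% of the difference in shares was left, 1.90 of 5.98 percentage points. The 1.90 points rest on 8 sub-clusters with 7562 GDSS and 1641 Yorkshire cells, the 5.98 on all sub-clusters. CD9 is itself a leading gene of sub-cluster 4, so this weighting conditions in part on CD9, and without thinning 10.6 points were left. With sub-clusters made without CD9, 14.6% of the difference was left at resolution 0.5 and 63.9% at resolution 0.3, and at resolution 0.8, over fewer GDSS cells, the difference was −0.387 points, of the other sign. The make-up of the FAP-like cells thus cannot be told apart from a difference within sub-clusters, and a difference between the breeds stays open and was not tested.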
